A study of Mus musculus with 6 samples.

How the data were processed

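Single-cell T-cell receptor sequencing was done on tetramer-sorted thymic iNKT cells in 6 libraries, 3 from WT and 3 from B7KO BALB/c mice. Per the labels' protocols, the cells were captured with 10x Genomics 5′ chemistry, version 2, on 1 lane per sample with up to 6000 cells loaded. The submitters' processing notes name Cell Ranger 6.1.1, bcl2fastq 2.20.0 and STAR 2.7.2a and the builds mm10 and GRCm38, without saying which served which step; other upstream settings are not given in the sources used here. The authors deposited 1 table per library that lists assembled receptor chains, each with its cell barcode, V and J gene, CDR3 sequence and the counts of its reads and unique molecular identifiers (UMIs), as raw counts per the file headers. Each table held only chains marked as from a cell, high in confidence, full in length and productive (0 exceptions in 30817 chains) and only TRA and TRB chains. An analysis of non-productive TRB chains had been fixed in advance and could not be run for that reason. Gene expression in the same cells was not analysed here.

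What was counted from the tables is cells, or clonotypes, per feature and library. D and N copies and alleles of V genes were merged, so that TRAV11 includes TRAV11D. The name TRBV12-2+TRBV13-2 (6357 chains) was read as TRBV13-2, because all 6357 had the CDR1 and CDR2 of TRBV13-2; 761 chains had the name TRBV13-2 itself. That reading was chosen after seeing the data, and keeping the joint name as a gene of its own is an alternative. An iNKT-typed cell had exactly 1 TRB chain and 1 or 2 TRA chains, at least 1 of them TRAV11–TRAJ18. Left out of this population were 3566 cells with 1 TRB chain and no TRA chain, 742 barcodes with 2 or more TRB chains, 940 with TRA alone, and 1540 cells whose TRA chains had neither TRAV11 nor TRAJ18. Also left out were cells with TRAV11 or TRAJ18 but not both in 1 chain, 3, 12 and 22 in the WT libraries and 5, 2 and 6 in the B7KO libraries. Doublets were treated only by the exclusion of barcodes with 2 or more TRB chains. At most 18 barcodes were shared by 2 libraries.

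The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on cells per feature, B7KO against WT, with the total cells of the population as offset, no further scaling and no covariate. Features with at least 20 cells over the 6 libraries were tested, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Families were TRBV genes, TRBJ segments, TRBV–TRBJ combinations, CDR3β lengths, CDR3α sequences, CDR3β sequences, the TRAV of a second TRA chain and the TRBV of cells without the canonical α chain. Single values per library (shares, mean length, richness, UMIs, overlap) were compared by exact permutation of the libraries, two-sided except for overlap, with adjustment over the 13 planned values. The lengths within TRBV genes and related values formed a family of 12, and the shares by clonotype one of 7. Replicates are libraries, never cells. Clonotypes for richness and for expanded shares (2 or more cells) were defined by TRBV, TRBJ and the CDR3 nucleotide sequences of both chains. Each library was thinned to 1156 cells, or to 1941 in the counts over all cells with 1 TRB chain. For expanded shares this was done in 100 seeded draws, and for richness by exact rarefaction. Repertoire overlap is the Morisita–Horn index of TRBV, TRBJ and CDR3β amino acids. Hydrophobic residues were I, L, V, F, W, M and C at position 6 or 7 of CDR3β.

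These tests, the lists below and most alternatives were chosen before the data were examined. The lists were Vβ8 (TRBV13-1, TRBV13-2 and TRBV13-3), Vβ7 (TRBV29), Vβ2 (TRBV1) and the genes deleted by endogenous superantigens (TRBV26, TRBV12-1, TRBV12-2, TRBV16 and TRBV15). Markers of cell types were TRAV11–TRAJ18 for iNKT cells, TRAV1–TRAJ33 for MAIT cells, TRAV10–TRAJ50 for Vα10 NKT cells and immunoglobulin chains for B cells, which could not be tested because the tables hold only TRA and TRB chains. In current gene names the Vα10 chain is TRAV13–TRAJ50, so that TRAV13–TRAJ50 was counted as well, after seeing the data. Every tested member of the lists is named. Of other TRBV genes, TRBJ segments, combinations, lengths and second TRAV genes, up to 5 per direction past the threshold with the largest log2 folds are named, and the 3 most used. For CDR3 sequences these are the 3 most used and up to 5 per direction past the threshold. In a family without a call, the 3 with the smallest p-values are named as having missed it.

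The alternatives were TMM and RLE scaling, DESeq2 1.42.0, no filter on rare features, the replicate number as a block, each library left out in turn, chains with at least 3 UMIs, each clonotype counted once, cells with 2 TRB chains kept and all cells with exactly 1 TRB chain. For single values they were also a CDR3α length of 15 amino acids as part of the definition, clonotypes from TRB alone, no thinning, a Jaccard index, and overlap of CDR3β alone. The count by TRB clonotype, over all cells with 1 TRB chain, was added after the tests on cells had given no call and after the differing shares of cells without TRA had been seen. Its own alternatives also cover chains with at least 10 UMIs, iNKT-typed cells alone, clonotypes of 1 cell alone, and near copies left out (1 base from a clonotype at least 10 times larger). RLE scaling and counting each clonotype once gave no value for CDR3β sequences and second TRAV genes. With TMM and RLE scaling the median log2 fold moved from 0.45 to 0.21 and 0.08 for TRBV by cell, from -0.20 to -0.06 and -0.19 for TRBJ, and from 0.21 to -0.10 and -0.18 for combinations. For lengths it moved from -0.48 to -0.27 and -0.55 and for CDR3α sequences from 0.66 to 0.49 and 0.32. For second TRAV genes it moved from -1.28 to 1.26 with TMM scaling, and for CDR3β sequences from -6.08 to -6.82. By clonotype the TRBV median was 0.08, 0.04 and -0.03, and that of combinations 0.06, 0.00 and -0.03.

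The tests were checked on 100 simulated tables per setting, drawn from the means, spreads and library totals of the real ones. With 2 of the 10 TRBV genes changed, 1% of changes of 1.5-fold, 5.5% of 2-fold and 28% of 4-fold were recovered by cell, and 44.5%, 72% and 96.5% by clonotype. For TRBJ segments, 3%, 13% and 51.5% were recovered by cell and 82%, 98% and 100% by clonotype. For combinations, with 5 of 53 changed, the shares were 0.2%, 0.2% and 2.8% by cell and 10.6%, 50.8% and 93% by clonotype. For lengths they were 2.5%, 10% and 38% by cell and 69%, 89.5% and 98% by clonotype. Shares sum to a total, so a strong change in some genes moves the rest. By clonotype, an average of 0.21 unchanged TRBV genes per table were called beside 1.5-fold changes, 0.65 beside 2-fold changes and 2.29 beside 4-fold changes, against 0.02 with no change at all.

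Depth per library was 39808 to 90389 UMIs over 2391 to 3299 barcodes. Intervals for shares within a library are 95% Wilson intervals, and the limit given for a count of 0 is 3 counts of the total. Both cover counting error alone. Gene positions come from the GENCODE mouse release 21 annotation of GRCm38. Permutation tests and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.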

Results

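T-cell receptor (TCR) chains were read from single thymic invariant natural killer T (iNKT) cells of BALB/c mice, in 3 wild-type (WT) libraries and 3 libraries from mice without Cd80 and Cd86 (B7KO). CD80 and CD86, the B7 molecules, are the costimulatory ligands that antigen-presenting cells offer to CD28 and CTLA-4 on T cells. iNKT cells recognise glycolipids on CD1d through an α chain that joins TRAV11 to TRAJ18 (Vα14–Jα18 in the older naming) and a β chain that in mice mostly uses Vβ8 (TRBV13), Vβ7 (TRBV29) or Vβ2 (TRBV1). Thymocytes binding the PBS57–CD1d tetramer were sorted to hold CD44low and CD44high cells at 50% each, and 1 capture lane was loaded per sample. The comparison set the receptor repertoire of B7KO cells against that of WT cells. The libraries hold receptor chains alone, so the loss of Cd80 and Cd86 (chromosome 16, GRCm38, 38455561 to 38496335 and 36603869 to 36666081) could not be checked in them. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries.

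The tables held 30817 productive chains in 17034 cell barcodes, with 2953 to 3299 barcodes in each WT library and 2391 to 2689 in each B7KO library. Unique molecular identifiers (UMIs) summed to 54016, 42515 and 71663 in WT replicates 1 to 3 and to 90389, 39808 and 52430 in B7KO replicates 1 to 3. A cell was typed as iNKT when it had exactly 1 TRB chain and 1 or 2 TRA chains, at least 1 of them TRAV11–TRAJ18. This gave 1811, 1634 and 2360 cells in the WT libraries and 1156, 1558 and 1677 in the B7KO libraries. The median TRB chain of such a cell had 12 ± 2.65 UMIs (SD, n = 3) in WT and 13.7 ± 3.06 (SD, n = 3) in B7KO (two-sided exact permutation p = 0.6). With 3 libraries against 3, no two-sided permutation p under 0.1 can be reached, so none of the exact tests of B7KO against WT could pass 0.05.

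The TRAV11–TRAJ18 chain marked 95.4% ± 1.41 (SD, n = 3) of WT cells with 1 TRB chain and a TRA chain, against 81.6% ± 29.1 (SD, n = 3) in B7KO (two-sided exact permutation p = 1). Trav11 lies on chromosome 14 of GRCm38 at 53519303 to 53519859 and Traj18 at 54200777 to 54200842. The wide B7KO spread came from B7KO replicate 1, where 1232 of 2594 cells with 1 TRB chain carried the same β chain (TRBV13-1, TRBJ2-7, CDR3 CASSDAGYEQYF). That is 47.5% of them (95% Wilson interval, 45.6% to 49.4%), and 1225 of these cells had a TRAV13D-3–TRAJ50 α chain in place of TRAV11–TRAJ18. Without that library the B7KO share was higher than the WT share by 2.95 percentage points. Cells without the canonical chain numbered 59, 61 and 131 in the WT libraries and 1244, 22 and 23 in the B7KO libraries. Among them TRBV13-1 took 29.2% ± 22.7 (SD, n = 3) in WT and 40.4% ± 51.0 (SD, n = 3) in B7KO, a log2 fold of 0.52. That direction came from the clone of B7KO replicate 1: the fold was -1.35 without that library and -0.51 with each clonotype counted once. TRBV13-2 had a log2 fold of -0.53 (0.26 with each clonotype counted once and 0.09 without WT replicate 3), and TRBV29 one of -0.01 that was 0.07 with RLE scaling. In edgeR 0 of these 3 genes passed, 0 had an unadjusted p under 0.05, and DESeq2 called 0. In WT replicate 3, 106 of the 131 cells used TRBV13-2. Of the 324 cells of the TRBV13-2 clonotype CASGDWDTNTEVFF there, 225 had TRAV11–TRAJ18 and 3 had no TRA chain. The rest had a TRA chain but not TRAV11–TRAJ18, so part of the 131 belonged to a clone whose other cells were iNKT-typed. Of the markers of other cells, the MAIT chain TRAV1–TRAJ33 was in 0 barcodes, which allows up to 0.111% to 0.156% of the barcodes of a library that had a TRA chain. The Vα10 NKT marker, fixed as TRAV10–TRAJ50, was in 0 barcodes under that name. Under the current name, TRAV13–TRAJ50, it was in 19, 28 and 5 barcodes of the WT libraries and in 1238, 10 and 2 of the B7KO libraries. B cells could not be looked for, since the tables hold only TRA and TRB chains.

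Counted over iNKT-typed cells, Vβ8 genes made up most of the repertoire in both genotypes, and no TRBV gene passed the test against the spread between libraries. TRBV13-2 (Vβ8.2) was used by 44.7% ± 19.6 (SD, n = 3) of WT cells and 53.3% ± 15.0 (SD, n = 3) of B7KO cells, a log2 fold of 0.25 that was -0.05 with TMM and -0.02 with RLE scaling. TRBV13-1 (Vβ8.3) was at 25.8% ± 17.0 and 13.9% ± 3.54 (SD, n = 3 each), and TRBV13-3 (Vβ8.1) at 4.33% ± 3.36 and 6.76% ± 3.07. TRBV29 was at 10.1% ± 7.38 in WT and 16.3% ± 6.35 in B7KO, and TRBV1 at 13.3% ± 10.7 and 6.51% ± 1.86 (SD, n = 3 each). Of the other genes the most used were TRBV31, TRBV17 and TRBV5, each under 2% in every library, with log2 folds of 1.56, 0.21 (-0.21 with RLE scaling) and 1.80. In edgeR 0 of the 10 TRBV genes passed and 0 had an unadjusted p under 0.05, and DESeq2 called 0. The log2 folds of TRBV1, TRBV13-1 and TRBV29 were -1.03, -0.88 and 0.69, and without WT replicate 1 they were -0.18, -0.19 and 0.20. Adjusted over the list alone, 0 of the 3 Vβ8 genes passed, and neither did TRBV29 or TRBV1. Without WT replicate 2, edgeR called 1 gene, TRBV5 (log2 fold 4.46, adjusted p = 0.0129), with 0 and 1 such cells in the WT libraries left. The summed Vβ8 share was 74.8% ± 7.11 in WT and 74.0% ± 9.19 in B7KO (SD, n = 3 each, two-sided exact permutation p = 1). For Vβ7 and Vβ2 the exact permutation p was 0.4 and 0.5.

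Large clones set much of that spread. A clonotype is here a set of cells of a library with the same TRBV, TRBJ and CDR3β nucleotide sequence. Clonotypes of more than 20 cells held 53.5%, 16.2% and 49.8% of the cells with 1 TRB chain in WT replicates 1 to 3 and 49.7%, 46.9% and 15.4% in B7KO replicates 1 to 3. In B7KO replicate 1, 1232 of these 1290 cells were of the clonotype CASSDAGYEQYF. That clonotype had 0 iNKT-typed cells, so it adds nothing to the spread over iNKT-typed cells. In B7KO replicate 2 a single TRBV13-2–TRBJ2-1 clonotype, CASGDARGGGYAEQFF, held 796 of 1941 cells, 41.0% of them (95% Wilson interval, 38.8% to 43.2%). In WT replicate 1 the largest clonotype was TRBV1–TRBJ1-1 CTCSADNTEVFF with 356 of 2920 cells (12.2%, 95% Wilson interval 11.1% to 13.4%). WT replicate 3 was led by TRBV13-2–TRBJ1-1 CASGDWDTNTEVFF with 324 of 3114 cells (10.4%, 9.38% to 11.5%). The largest clonotypes of WT replicate 2 and B7KO replicate 3 held 2.60% (2.06% to 3.28%) and 6.36% (5.41% to 7.47%) of the cells. Barcodes with 2 TRB chains are not counted here; in WT replicate 2 the most common pair of such chains was in 100 barcodes, more than the 68 cells of its largest clonotype.

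**Figure D1:**
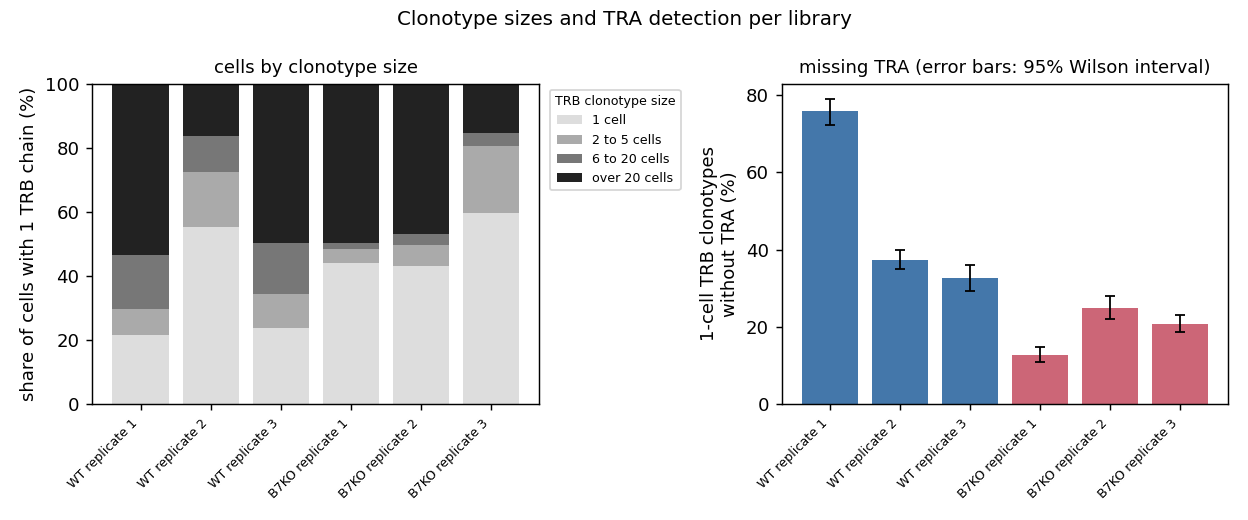
Left, the share of cells with 1 TRB chain (%) in TRB clonotypes of 1, 2 to 5, 6 to 20 and over 20 cells, stacked for each of the 6 libraries. Right, the share of 1-cell TRB clonotypes without a TRA chain (%) with its 95% Wilson interval, from 32.6% to 75.8% in the WT libraries (blue) and from 12.7% to 24.9% in the B7KO libraries (red).

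Counting each TRB clonotype once, over all cells with 1 TRB chain, TRBV29 rose and TRBV1 fell in B7KO. TRBV29 (Trbv29, chromosome 6, GRCm38, 41271394 to 41271881) went from 15.5% ± 2.83 of the WT clonotypes to 21.8% ± 0.885 of the B7KO clonotypes (SD, n = 3 each). Its log2 fold was 0.46 (SE 0.12, edgeR adjusted p = 0.0217). TRBV1 (Trbv1, chromosome 6, 40891229 to 40891885) went from 9.98% ± 0.344 to 7.62% ± 0.270 (SD, n = 3 each), a log2 fold of -0.39 (SE 0.08, edgeR adjusted p = 0.0133). The abundant TRBV13-2 was at 44.0% ± 2.59 and 44.2% ± 0.657, a log2 fold of 0.00 that was -0.12 with RLE scaling. TRBV13-1 was at 18.6% ± 4.41 and 13.5% ± 0.95 (log2 fold -0.43, edgeR adjusted p = 0.0547), and TRBV13-3 at 6.0% ± 0.709 and 7.74% ± 0.75 (0.37, edgeR adjusted p = 0.0529). TRBV31, TRBV5 and TRBV19 had log2 folds of 0.47, 0.00 and -0.32. This count covers 6972 clonotypes, 786 to 1662 per library, and was chosen after the counts of cells had been seen; it is 1 of several ways of counting that were tried.

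In edgeR 2 of the 10 genes passed by clonotype, 1 higher and 1 lower, and DESeq2 called 3, the same genes and TRBV13-1. With RLE scaling 0 were higher and 2 lower, TRBV1 and TRBV13-1. Adjusted over the list alone, 2 of the 3 Vβ8 genes passed, TRBV13-1 as lower and TRBV13-3 as higher; TRBV29 and TRBV1, lists of 1 gene each, passed too. Restricted to clonotypes of iNKT-typed cells, TRBV29 had a log2 fold of 0.37 (edgeR adjusted p = 0.162) and TRBV1 one of -0.31 (edgeR adjusted p = 0.124). There 0 genes passed in edgeR, with 3 at an unadjusted p under 0.05. Counting each pair of α and β chains once over the same cells, as fixed beforehand, also gave 0 calls in edgeR, with 2 genes at an unadjusted p under 0.05. Leaving out a library gave 4 calls without WT replicate 1 and 1 call without WT replicate 2, WT replicate 3 or B7KO replicate 1. Without B7KO replicate 2 or B7KO replicate 3 there were 0 calls in edgeR; TRBV29 was then at an adjusted p of 0.0677 and 0.0609, and TRBV1 at the same values. Over all 17 alternatives the adjusted p of TRBV29 ran from 0.000298 to 0.162 and that of TRBV1 from 0.00285 to 0.124.

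**Figure D2:**
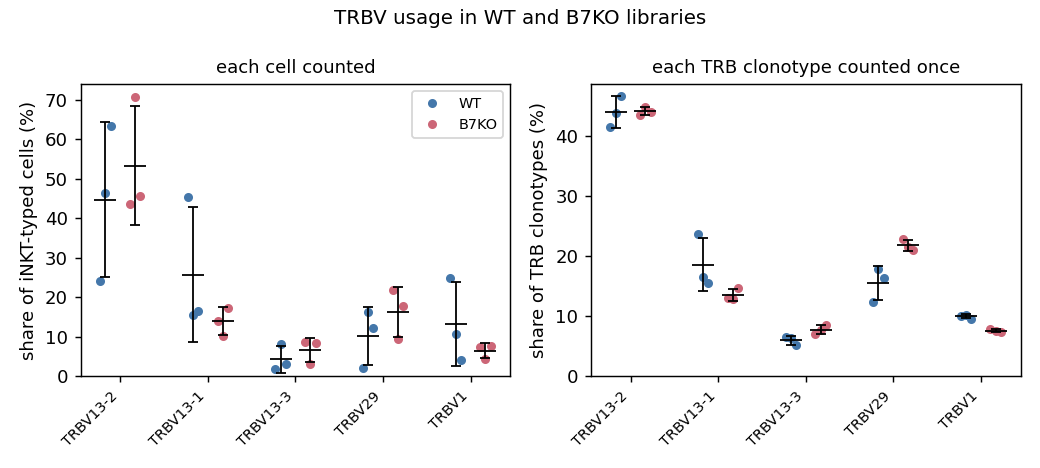
Share of iNKT-typed cells (left, %) and of TRB clonotypes (right, %) with each of the 5 TRBV genes of the fixed lists, 1 point per library for WT (blue) and B7KO (red), with the mean and SD in black. By clonotype the 3 B7KO libraries lie between 21.1% and 22.8% for TRBV29, above the WT libraries at 12.3% to 17.8%.

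Among the TRBJ segments, TRBJ1-5 had the smallest p-value in both counts, with lower shares in B7KO, and did not pass in edgeR in either. It was used by 10.4% ± 0.844 of WT and 3.98% ± 1.68 of B7KO iNKT-typed cells (SD, n = 3 each), a log2 fold of -1.38 (edgeR adjusted p = 0.126). By clonotype it was at 9.64% ± 2.75 and 5.45% ± 0.658, a log2 fold of -0.72 (edgeR adjusted p = 0.0725). TRBJ2-1 was at 4.45% ± 3.44 of WT and 22.1% ± 24.9 of B7KO cells (log2 fold 2.31, edgeR adjusted p = 0.163), with 103, 792 and 111 such cells in B7KO replicates 1 to 3. With a library left out, its fold ran from 0.80 to 2.80. TRBJ1-1, TRBJ2-7 and TRBJ1-4 had log2 folds of -1.05, 0.70 and 0.69 by cell. Without WT replicate 1, where TRBJ1-1 was at 31.9%, its fold was -0.58. By clonotype the rarer TRBJ1-6 was at 1.28% ± 0.329 and 1.96% ± 0.187 (0.67) and TRBJ2-4 at 7.43% ± 0.0845 and 8.97% ± 0.429 (0.28), each at an edgeR adjusted p of 0.0725. TRBJ1-1, TRBJ2-7 and TRBJ2-5 had log2 folds of -0.22, 0.16 and 0.04 (-0.02 with RLE scaling for TRBJ2-5). WT and B7KO libraries did not overlap for 6 of the 12 segments by clonotype, where chance gives 10%, and by cell only for TRBJ1-5 and TRBJ2-2. The TRBJ2 cluster as a whole held 40.8% ± 8.09 of WT and 64.9% ± 11.1 of B7KO cells, and 51.1% ± 2.18 and 59.2% ± 2.64 of the clonotypes (SD, n = 3 each). In both counts the libraries of the genotypes did not overlap, and the two-sided exact permutation p was 0.1, the smallest possible, or 0.65 and 0.175 after adjustment over the 13 and 7 values of each family.

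By cell, edgeR called 0 of the 12 TRBJ segments, with 2 at an unadjusted p under 0.05, while DESeq2 called 3, TRBJ1-5 and TRBJ1-2 as lower and TRBJ2-7 as higher (TRBJ1-2 is named here after its values were seen). TRBJ1-5 also passed in edgeR with RLE scaling (adjusted p = 0.00230) and over all cells with 1 TRB chain (adjusted p = 0.0189); its adjusted p over 15 alternatives ran from 2.80e-06 to 0.271. By clonotype edgeR called 0 segments, with 6 at an unadjusted p under 0.05, and DESeq2 called 1, TRBJ1-5. Without WT replicate 1 and without WT replicate 2, edgeR called TRBJ1-5 as well (adjusted p = 0.0142 and 0.0104).

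**Figure D3:**
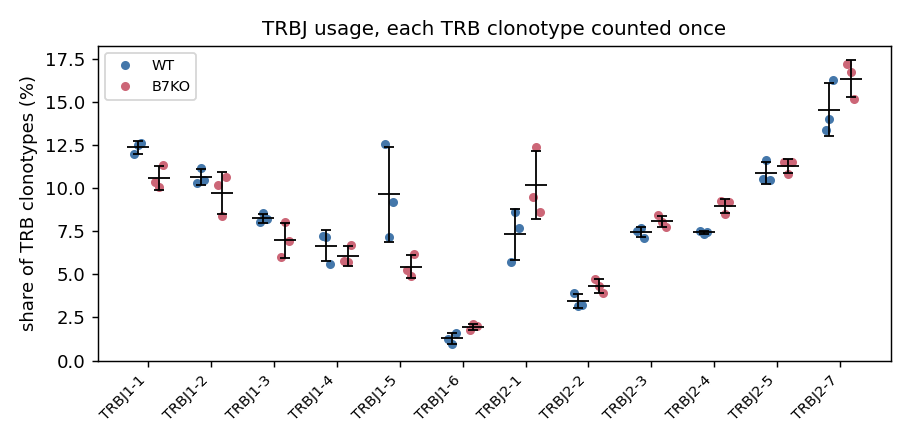
Share of TRB clonotypes (%) with each TRBJ segment, 1 point per library for WT (blue) and B7KO (red), with the mean and SD in black. TRBJ1-5 lies at 7.16% to 12.6% in the WT libraries and at 4.91% to 6.18% in the B7KO libraries.

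Of the TRBV–TRBJ combinations, TRBV13-1 joined to TRBJ1-5 fell in B7KO and TRBV13-2 joined to TRBJ2-1 rose, again by clonotype and, in edgeR, not by cell. TRBV13-1/TRBJ1-5 went from 3.30% ± 1.46 of the WT clonotypes to 0.978% ± 0.298 of the B7KO clonotypes (SD, n = 3 each), from 39, 37 and 25 clonotypes in the WT libraries to 12, 6 and 19 in the B7KO libraries. Its log2 fold was -1.58 (SE 0.29, edgeR adjusted p = 9.65e-06). TRBV13-2/TRBJ2-1 went from 2.71% ± 0.603 to 4.51% ± 1.32, a log2 fold of 0.62 (SE 0.20, edgeR adjusted p = 0.0485). It was at 3.84%, 6.03% and 3.66% in B7KO replicates 1 to 3, and the largest clone of B7KO replicate 2 has the same V and J genes. The most used combinations, TRBV13-2 with TRBJ2-7, TRBJ2-5 and TRBJ1-1, had log2 folds of -0.07, -0.03 and -0.12. By cell the same 2 combinations had log2 folds of -2.61 and 3.96 and TRBV1/TRBJ1-1 one of -3.47, each at an edgeR adjusted p of 0.273. TRBV13-2 with TRBJ1-1 and with TRBJ1-2 had log2 folds of -0.29 and -1.25 by cell. The first of these was 0.78 without WT replicate 3 and 0.07 without B7KO replicate 2. B7KO replicate 2 held 752 TRBV13-2/TRBJ2-1 cells, 700 of them of its largest clonotype, against 41 and 50 in the other B7KO libraries. The TRBV1/TRBJ1-1 cells numbered 388 in WT replicate 1 and 23 and 14 in the other WT libraries.

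By cell, edgeR called 0 of 53 combinations, with 7 at an unadjusted p under 0.05, and DESeq2 called 8, 1 higher and 7 lower. TRBV13-1/TRBJ1-5 was among the lower ones (log2 fold -3.49, DESeq2 adjusted p = 0.000118), and its libraries did not overlap by cell. By clonotype edgeR called 2 of 53, 1 higher and 1 lower. With TMM or RLE scaling, in DESeq2 and with near copies left out, TRBV13-1/TRBJ1-5 was called and TRBV13-2/TRBJ2-1 was not, 0 higher and 1 lower. Under the replicate block 0 combinations were called by clonotype, so both calls were lost. TRBV13-2/TRBJ2-1 passed in 3 of its 17 alternatives and TRBV13-1/TRBJ1-5 in 15. Among clonotypes of iNKT-typed cells 0 combinations passed in edgeR, with 3 at an unadjusted p under 0.05, and TRBV13-1/TRBJ1-5 had a log2 fold of -1.92 (adjusted p = 0.0779). The adjusted p over 17 alternatives ran from 7.87e-06 to 0.0779 for TRBV13-1/TRBJ1-5 and from 0.0371 to 0.454 for TRBV13-2/TRBJ2-1. The second passed without B7KO replicate 1 or B7KO replicate 3 and was lost when any of the other libraries was left out, with an adjusted p of 0.346 without B7KO replicate 2. Without B7KO replicate 1 or without WT replicate 2, 3 combinations were called each time. Named after their values were seen, the added ones were TRBV1/TRBJ1-1 (log2 fold -1.22) in the first case and TRBV13-2/TRBJ1-5 (-0.79) and TRBV29/TRBJ1-4 (1.07) in the second.

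The mean CDR3β length by cell was 13.95 ± 0.0576 amino acids in WT and 14.5 ± 0.522 in B7KO (SD, n = 3 each), with the conserved ends included. The libraries did not overlap, and the two-sided exact permutation p was 0.1 (0.65 adjusted over 13 values). The difference of 0.566 was 0.266 without B7KO replicate 2, the library with the large clone of 16 amino acids. Over all cells with 1 TRB chain it was 0.173, and the genotypes overlapped, with B7KO replicate 1 at 13.2 and the WT libraries at 13.9, 14.0 and 14.0. By clonotype the means were 14.19 ± 0.0957 and 14.23 ± 0.0244 (two-sided exact permutation p = 0.5). Loops of 16 amino acids, the length of the large clone in B7KO replicate 2, made up 15.0% ± 3.62 of WT and 27.1% ± 21.4 of B7KO cells (log2 fold 0.85); loops of 14 and 15 amino acids had log2 folds of -0.53 and 0.58. In edgeR 0 of 9 lengths passed by cell and 0 by clonotype, none had an unadjusted p under 0.05 in either count, and DESeq2 called 0 in both. By clonotype the log2 folds of 13, 14, 15 and 17 amino acids were -0.11, -0.03, 0.11 and 0.14. Within TRBV13-2, TRBV13-3 and TRBV29 the mean length by cell was higher in each B7KO library than in any WT library, by 0.688, 0.629 and 0.196 amino acids (two-sided exact permutation p = 0.1, adjusted 0.3 over 12 values). By clonotype the libraries overlapped for these 3 genes, with differences of 0.121, -0.0658 and 0.108. TRBV13-1, without overlap there, was shorter in B7KO by clonotype, with a difference of -0.0945 (two-sided exact permutation p = 0.1, adjusted 0.3). A hydrophobic residue at position 6 or 7 of the loop, counted from the conserved cysteine as 1, was present in 21.3% ± 5.47 of WT and 19.4% ± 8.13 of B7KO cells (SD, n = 3 each, two-sided exact permutation p = 0.7). By clonotype the shares were 18.6% ± 0.986 and 20.7% ± 1.44 (p = 0.1, exact permutation, adjusted 0.175), the opposite order.

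The α chain was nearly fixed in both genotypes. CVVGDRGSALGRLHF made up 93.8% ± 1.09 of the TRAV11–TRAJ18 chains of WT cells and 90.7% ± 1.67 of those of B7KO cells (SD, n = 3 each), a log2 fold of -0.05. The variants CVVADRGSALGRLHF and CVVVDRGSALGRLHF, which differ from it in the residue after the first 3, were at 3.30% ± 1.24 and 2.29% ± 0.454 in WT and at 4.48% ± 0.768 and 3.66% ± 1.17 in B7KO (log2 folds 0.45 and 0.69). In edgeR 0 of 5 sequences passed, with 1 at an unadjusted p under 0.05, and DESeq2 called 0; the adjusted p was 0.185, 0.259 and 0.185. Counting each clonotype once, the log2 folds of the 3 sequences were 0.10, -0.57 and -0.42, the opposite order.

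A second TRA chain was present in 5.66% ± 6.11 of WT and 2.69% ± 1.22 of B7KO iNKT-typed cells (SD, n = 3 each, two-sided exact permutation p = 0.8). The WT libraries were at 1.44%, 2.88% and 12.7%, and the difference was 0.538 percentage points without WT replicate 3 and 0.747 with each clonotype counted once, the opposite sign. Among these second chains TRAV1 made up 0.446% ± 0.772 in WT and 19.0% ± 1.35 in B7KO, a log2 fold of 4.44 that missed the threshold (edgeR adjusted p = 0.107). These were 0, 0 and 4 cells in the WT libraries and 7, 4 and 11 in the B7KO libraries. It passed with chains of at least 3 UMIs (log2 fold 4.09, adjusted p = 0.000296). Without WT replicate 3 no WT cell with it was left, so no fold is given there. Its adjusted p over 11 alternatives reached 0.552. TRAV12-3, TRAV11, TRAV15-1-DV6-1 and TRAV9-4 had log2 folds of -1.98, -1.28, 1.77 and -1.46 (1.26 with TMM scaling for TRAV9-4). The fold of TRAV12-3 was 1.90 without WT replicate 3, and that of TRAV9-4 was 3.94 without WT replicate 1. Each rests on 0 and 1 such cells in the WT libraries left. The B7KO libraries held 2, 2 and 3 cells with TRAV12-3 and 2, 0 and 6 with TRAV9-4. Of the 5 genes edgeR called 0, with 1 at an unadjusted p under 0.05, and DESeq2 called 0. TRAV12-3 was the second chain in 225 cells of WT replicate 3 and in at most 3 of any other library; the clonotype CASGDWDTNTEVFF of WT replicate 3 held 314 cells with TRAV12-3–TRAJ6.

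The share of cells in which no TRA chain was found differed between the libraries. Of cells with 1 TRB chain, 1047, 907 and 601 in the WT libraries and 189, 359 and 463 in the B7KO libraries had no TRA chain, and such cells enter no count of iNKT-typed cells. Among clonotypes of 1 cell the share without TRA was 75.8% (95% Wilson interval, 72.3% to 79.0%), 37.3% (34.9% to 39.9%) and 32.6% (29.3% to 36.1%) in WT. In B7KO it was 12.7% (10.9% to 14.8%), 24.9% (22.0% to 27.9%) and 20.8% (18.6% to 23.1%). The genotypes did not overlap, which chance gives in 10% of splits. The median TRA chain had 4.0 ± 1.0 UMIs in WT and 4.67 ± 0.577 in B7KO (SD, n = 3 each, two-sided exact permutation p = 0.7).

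Expanded clonotypes, defined by both chains and after thinning each library to 1156 iNKT-typed cells, held 69.1% ± 26.5 of WT and 35.8% ± 22.8 of B7KO cells (SD, n = 3 each, two-sided exact permutation p = 0.2). This leaves out the largest clonotype of B7KO replicate 1, which lacks the canonical α chain. Over all cells with 1 TRB, thinned to 1941 cells per library and with the TRB nucleotide sequence alone, the difference in the expanded clonotype share was -14.2 percentage points in place of -33.3. This count was added after the data were seen, and it changes the depth as well as the cells and the definition. The shares were then 76.9%, 42.2% and 74.2% in WT and 55.1%, 56.9% and 38.8% in B7KO. At 1156 iNKT-typed cells the number of different clonotypes was 451 ± 302 in WT and 797 ± 271 in B7KO (two-sided exact permutation p = 0.2). In the count over all cells with 1 TRB, at 1941 cells, it was 568, 1283 and 637 in WT and 907, 896 and 1367 in B7KO. The difference in clonotype richness with the TRB nucleotide sequence alone was there 227 in place of 347. With a library left out, the difference at 1156 iNKT-typed cells ran from 218 to 513 clonotypes in richness and from -47.9 to -22.2 percentage points in the expanded share. Among iNKT-typed cells, the most used CDR3β sequences were mostly found in single libraries. The first of them, TRBV13-2/TRBJ2-1 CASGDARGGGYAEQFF, was in 701 iNKT-typed cells of B7KO replicate 2 and in none of the other libraries. TRBV13-1/TRBJ2-4 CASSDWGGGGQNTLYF was in 253 cells of WT replicate 1 and in none elsewhere, and TRBV1/TRBJ1-1 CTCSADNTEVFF in 225 cells of WT replicate 1 and 9 of WT replicate 2. In WT replicate 2, 100 more barcodes had it beside a second TRB chain and were left out. The smallest p-values belonged to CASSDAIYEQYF and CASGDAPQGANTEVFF, with 91 and 81 cells of B7KO replicate 3, and to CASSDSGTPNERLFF, with 65 cells of B7KO replicate 2. In edgeR 0 of 49 sequences passed, 0 had an unadjusted p under 0.05, and DESeq2 called 0; the adjusted p of all 6 was 0.277. Repertoires barely overlapped: the Morisita–Horn index averaged 0.00468 over the 6 pairs of libraries of a genotype and 0.00254 over the 9 pairs across genotypes (one-sided exact permutation p = 0.4 over 10 splits). The difference was 0.00214, and -0.00335 without WT replicate 1.

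Vβ chains that endogenous superantigens delete in BALB/c mice (TRBV26, TRBV12-1, TRBV12-2, TRBV16 and TRBV15) were rare among iNKT-typed cells of both genotypes. They were in 17 of 1811 iNKT-typed cells of WT replicate 1 (0.939%, 95% Wilson interval 0.587% to 1.5%), in 3 of WT replicate 3 and in 1 of B7KO replicate 1. With each clonotype counted once the share was 0.412% in WT replicate 1, of 243 clonotypes, and 0.468% in WT replicate 3. The cells of WT replicate 1 were thus of a single clone, and the interval, which takes cells as independent, is too narrow for it. The other libraries had 0, which allows up to 0.184% in WT replicate 2, 0.193% in B7KO replicate 2 and 0.179% in B7KO replicate 3. The means were 0.355% ± 0.509 and 0.0288% ± 0.0499 (SD, n = 3 each, two-sided exact permutation p = 0.4), and 1.64% ± 1.70 and 0.0268% ± 0.0464 in cells without the canonical α chain (p = 0.4, exact permutation). The latter rest on 2, 0 and 2 cells in WT and 1, 0 and 0 in B7KO, and the counts of 0 in B7KO replicates 2 and 3 allow up to 13.6% and 13%, too wide to call them rare there. None of the 5 genes reached 20 cells or clonotypes, so 0 were tested singly. Barcodes with 2 or more TRB chains enter none of these counts. Over all barcodes, at least 5 in every library held a TRBV15 chain. A count of 0 above thus does not mean that the library had no such chain. Intervals and limits for single libraries cover counting error alone.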

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

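Of the tests in this part, those on TRAV13–TRAJ50 cells, on missing TRA chains, on other cells and the splits of the libraries were chosen only after the results were seen. Those on TRB depth and on the Tcrb haplotype were set beforehand, although the values with at least 3 UMIs were known by then.

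B7KO replicate 1 held 1238 barcodes with a TRAV13–TRAJ50 chain, against 19, 28 and 5 in the WT libraries and 10 and 2 in the other B7KO libraries; 1225 of them belong to the clonotype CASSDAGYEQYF. The cells of that clonotype enter no count of iNKT-typed cells. Free RNA of a broken cell spread over droplets would give few UMIs per barcode; the median TRB chain of the clonotype had 24 UMIs against 16 in the other barcodes, a ratio of 1.5, which argues against it. Chains carried over from another library are argued against as well, since 0 barcodes elsewhere had that TRB sequence. A single expanded clone, of tetramer-binding cells or of others that passed the sort, stays open, and with 1 such library its relation to genotype was not tested.

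B7KO replicate 2 held 616 barcodes with a TRA chain and no TRB chain, against 24 to 116 in the other libraries. Of these, 615 had TRAV11–TRAJ18, and 592 carried the α chain of the library's largest clonotype, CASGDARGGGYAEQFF. That CDR3α nucleotide sequence is a common one. The largest iNKT clonotypes of WT replicate 3 and B7KO replicate 1 had it too. Among 1-cell clonotypes with TRAV11–TRAJ18 it was in a mean of 30.9% in the other libraries, so it does not by itself identify the clone in any single barcode. In B7KO replicate 2 itself it was in 1.98% of such clonotypes. Both shares lie far below 592 of 615, so how common the sequence is does not account for that number. Whether these barcodes belong to the largest clone was not tested. Barcodes with 2 or more TRB chains, which the main counts leave out, numbered 742 over all libraries, with 252 in WT replicate 2 and 187 in B7KO replicate 3. In WT replicate 2, 100 of them had the pair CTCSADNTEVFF and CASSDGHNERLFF, and in B7KO replicate 3, 60 had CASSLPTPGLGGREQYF and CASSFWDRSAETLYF.

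TRBV29 was higher and TRBV1 lower among the TRB clonotypes of B7KO. A Tcrb haplotype with other V coding sequences in B7KO is argued against, since 0 of 11 TRBV genes had a common V sequence that differed between the genotypes; only 1 of them, TRBV10, differs even from C57BL/6, so a haplotype with the same V coding sequences would not be seen. Unequal TRB depth stays open for both genes. With chains of at least 10 UMIs the log2 fold of TRBV1 was -0.55, past the bound set against this explanation, and that of TRBV29 was 0.37. TRBV1 cells held more TRB UMIs than TRBV13-2 cells, so such a cut keeps TRBV1 more readily. It kept 820 of 1662 clonotypes in WT replicate 2 and 754 of 926 in WT replicate 3. The cut itself can thus move the TRBV1 share unequally, and the test cannot decide for this gene. Cells other than iNKT cells stay open for both genes, whose log2 folds among clonotypes of iNKT-typed cells were 0.37 and -0.31: that of TRBV29 lies within its spread of the bounds set for either outcome, and that of TRBV1 only of the bound against this explanation. The rule that a bound must be passed by more than 1 standard error was itself set after these values were seen. Without that rule, both folds among iNKT-typed cells were past the bound set against cells other than iNKT cells. That of TRBV29 with at least 10 UMIs was then past the bound set against unequal depth. The genotype itself remains an open explanation.

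The share of 1-cell clonotypes without a TRA chain ran from 32.6% to 75.8% in WT and from 12.7% to 24.9% in B7KO. Low RNA capture in the cells without TRA stays open: their median TRB UMIs were 0.921 ± 0.0697 (SD, n = 6) of those of cells with TRA. That mean is past the bound set against this explanation, though not by more than 1 standard error. The ratios were 0.909, 1 and 0.875 in WT replicates 1 to 3 and 0.824, 0.917 and 1 in B7KO replicates 1 to 3. The lowest ratio thus belonged to B7KO replicate 1, the library with the lowest share without TRA. Another candidate explanation is that TRA chains were left out where a larger clonotype of the library carries the same chain. It fits the count set for it, though not past the threshold. In 5 of 6 libraries the α nucleotide sequence of the largest iNKT clonotype was rarer among the library's own 1-cell clonotypes than in the mean of the other libraries (two-sided exact sign-flip permutation p = 0.0938). Only 1-cell clonotypes with a TRAV11–TRAJ18 chain were counted for this. In WT replicate 1 that sequence was in 1.67% of them against a mean of 19.2% elsewhere. In WT replicate 2 it was in 14.2% against 14.6%, nearly equal, and B7KO replicate 1 was the exception, at 37.8% against 23.7%. The largest iNKT clonotypes of these 2 libraries held 48 and 27 cells, against 91 to 700 in the other libraries. If TRA chains were left out in this way, counts of iNKT-typed cells may miss 1-cell clonotypes unequally. The sign-flip test and the count of 5 of 6 take the libraries as independent, which they are not here. WT replicate 3 and B7KO replicates 1 and 2 had the same α sequence in their largest iNKT clonotypes. Each library also enters the mean that the others are set against.

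The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. For TRBV genes and for combinations by clonotype the real split gave 2 calls each and the highest other split 0, so 1 split reached the real count. In the other 10 families, with 0 calls, all 10 splits did, and the highest other count was 1, for lengths by clonotype.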

How the results depend on the processing

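Alternatives for the counts by TRB clonotype were chosen only after the results were seen, as were the joint gene name and some clonotype counts; the others were planned. Of 317 values of the comparisons under alternatives, 269 stayed the same, 5 went to 0 calls, 12 went from 0 calls to some, 17 were numbers of calls that moved by more than 1.5 times and 14 were differences that changed sign or, for 1 of them, went to 0. Numbers of calls were compared without regard to which genes were called: TRBV by clonotype kept 2 calls with RLE scaling, but these were TRBV1 (log2 fold -0.51) and TRBV13-1 (-0.55) in place of TRBV29 and TRBV1. Single values per library could only stay the same or change sign, since none could pass 0.05. For the named features 817 of 931 kept both, 28 lost and 25 gained a call, and 61 changed sign. Folds of exactly 0, of CDR3β sequences without their only library, are left out of the ranges of folds, as decided after they were seen. The non-productive TRB result was not run, and RLE scaling and single counting of clonotypes gave no value for CDR3β sequences and second TRAV genes. The cause was not tested for the changes given here, except where a large clone or fewer features or libraries enter by construction.

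By cell, calls of TRBJ segments went from 0 to 1 with RLE scaling, 3 in DESeq2 and 1 over all cells with 1 TRB chain, and those of combinations from 0 to 8 in DESeq2. Second TRAV genes went from 0 to 1 with at least 3 UMIs. With a library left out, calls ran from 0 to 1 for TRBV genes and for second TRAV genes, where the call came with no WT cell of the called gene left. By clonotype, TRBV calls went from 2 to 4 with at least 3 UMIs and with 1-cell clonotypes alone and to 0 among iNKT-typed cells; leaving out a library gave 0 to 4. TRBJ calls by clonotype went from 0 to 1 in DESeq2 and with 1-cell clonotypes alone, and to 0 to 1 with a library left out. Calls of combinations by clonotype went from 2 to 1 with TMM scaling, RLE scaling, DESeq2, no filter, at least 3 UMIs, at least 10 UMIs, 1-cell clonotypes alone and near copies left out, to 0 among iNKT-typed cells, and to 1 to 3 with a library left out.

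With the replicate block, TRBJ calls by clonotype went from 0 to 2 and those of combinations by clonotype from 2 to 0, and TRBV by clonotype kept 2 calls, TRBV29 and TRBV13-1 in place of TRBV29 and TRBV1. The correlations of same-numbered libraries went both ways. Over TRBV genes they were -0.14, 0.02 and -0.25 by cell and 0.38, -0.74 and -0.45 by clonotype. Over TRBJ segments they were 0.38, 0.63 and -0.39 by cell and 0.11, 0.24 and -0.30 by clonotype. Not every library correlated best with its own number, and by the labels the libraries share only a number. Under the replicate block the log2 folds of TRAV12-3 and TRAV9-4 were 0.68 and 0.45 and that of TRBV5 by clonotype 0.0595, each with the opposite sign.

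Differences of B7KO minus WT also changed sign, except that in TRB UMIs, which went to 0. The TRAV11–TRAJ18 share was 4.81 percentage points with each TRB clonotype counted once (-22.3 to 2.95 with a library left out). The Vβ8 share was 5.50 over all cells with 1 TRB chain (-5.85 to 3.31). The hydrophobic share was 1.27 with each clonotype and 2.12 with each TRB clonotype counted once (-4.97 to 2.81), and that of cells with 2 TRA chains 0.747 with each clonotype counted once (-5.08 to 0.538). With a library left out, the difference in TRB UMIs per cell ran from 0 to 3 and that in overlap from -0.00335 to 0.00562.

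Log2 folds that changed sign by cell were those of TRBV13-1 over all cells with 1 TRB chain (0.23) and of TRBV13-2 with TMM scaling (-0.0515), RLE scaling and DESeq2 (-0.0211 in both), each clonotype counted once (-0.0320) and the joint gene name kept (-0.0404). That of TRBV17 was -0.21 with RLE scaling, -0.22 in DESeq2, -0.29 with each clonotype counted once and -0.0505 over all cells with 1 TRB chain. Counting each clonotype once gave -0.00159 for loops of 16 amino acids and 0.10, -0.57 and -0.42 for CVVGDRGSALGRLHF, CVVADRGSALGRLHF and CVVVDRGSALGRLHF. TRAV9-4 was at 1.26 with TMM scaling and 0.95 in DESeq2. In cells without the canonical α chain, each clonotype counted once gave -0.51, 0.26 and 0.34 for TRBV13-1, TRBV13-2 and TRBV29, and TRBV29 was at 0.0743 with RLE scaling, 0.0898 in DESeq2 and 0.30 with at least 3 UMIs. With a library left out, the ranges that crossed 0 were -0.0429 to 0.59 (TRBV13-2), -0.35 to 1.91 (TRBV17), -0.99 to 0.78 (TRBV13-2/TRBJ1-1), -0.0216 to 1.15 (16 amino acids), -2.60 to 1.90 (TRAV12-3) and -2.49 to 3.94 (TRAV9-4). In cells without the canonical chain they were -1.35 to 1.13 (TRBV13-1), -1.51 to 0.0906 (TRBV13-2) and -1.26 to 1.31 (TRBV29).

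By clonotype, TRBV13-2 was at -0.0314 with TMM scaling, -0.12 with RLE scaling and in DESeq2, -0.0322 among iNKT-typed cells and -0.0127 with cells of 2 TRB chains kept. TRBV5 was at 0.0312 with at least 3 UMIs, 0.71 among iNKT-typed cells and 0.26 with cells of 2 TRB chains kept, and TRBJ2-5 at -0.0156 with RLE scaling and -0.0111 in DESeq2. With at least 10 UMIs, TRBV13-2 with TRBJ2-7, TRBJ2-5 and TRBJ1-1 were at 0.21, 0.11 and 0.0112. With a library left out, the ranges that crossed 0 were -0.0259 to 0.0446 (TRBV13-2), -0.22 to 0.33 (TRBV5), -0.21 to 0.0837 (TRBV13-2/TRBJ2-7), -0.0779 to 0.0265 (TRBV13-2/TRBJ2-5) and -0.24 to 0.0245 (TRBV13-2/TRBJ1-1). The depth of 1156 to 2360 iNKT-typed cells per library limits rare genes; those under 20 cells over all libraries were not tested.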

Other observations

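All tests in this part were chosen only after the results were seen, except that on runs of G.

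TRAV13–TRAJ50 cells were found in all 6 libraries. Over the cells with 1 TRB chain they formed 33 clonotypes, of which 31 used a TRBV13 gene (93.9%, 95% Wilson interval 80.4% to 98.3%). Among 133 other clonotypes, all from cells without the canonical α chain, 57.1% did (48.6% to 65.2%). The 33 were not restricted to such cells and may include cells that also had TRAV11–TRAJ18, so the groups are not alike. The intervals cover counting error alone, and the difference was not tested over libraries. The CDR3α sequence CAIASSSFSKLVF was in 18 of the 33 clonotypes and in all 6 libraries. TRAV13–TRAJ50 is the rearrangement of the Vα10 NKT cells known in mice, and B7KO replicate 1 held most of the cells in 1 clonotype while having only 4 clonotypes of this kind. The CDR3α of that large clonotype was another one, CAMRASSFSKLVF, which was in 3 of the 33 clonotypes.

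The Vβ use of expanded TRB clonotypes was set beside that of 1-cell clonotypes, and no gene passed after adjustment. The TRBV29 share was lower among clonotypes of 2 or more cells by a mean difference of -5.55 percentage points, in 6 of 6 libraries. The TRBV13-1 share was higher by 7.37 percentage points, also in 6 of 6. For both genes the two-sided exact sign-flip permutation p was 0.03125, the smallest possible over 6 libraries, and 0.0781 after adjustment over 5 genes, which misses the threshold. For TRBV13-2, TRBV1 and TRBV13-3 the p was 0.875, 0.875 and 0.9375.

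Among 1-cell clonotypes, TRBV1 cells held more TRB UMIs than TRBV13-2 cells, with medians of 20.7 ± 5.31 and 10.3 ± 2.58 (SD, n = 6), in 6 of 6 libraries (two-sided exact sign-flip permutation p = 0.03125). Cells of different TRBV genes may therefore be detected at unequal rates. The largest clone of B7KO replicate 2 has a run of 11 G in its CDR3β. The hypothesis that a long run of G goes with fewer TRB UMIs was tested in TRBV13-2 clonotypes of 1 cell with at least 7 G in a row; it was not decided, with a difference of -1.17 ± 1.47 UMIs (SD, n = 6; two-sided exact sign-flip permutation p = 0.25).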
